A study of Rattus norvegicus with 17 samples.

How the data were processed

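Total RNA from the livers of 17 male Wistar rats was labelled with biotin and hybridised to Affymetrix arrays, 1 array per animal, per the labels' protocols. The deposited values are probe set summaries on the log2 scale; RMA and the affy package are named in the submitters' processing notes, with versions not given in the sources used here. RMA corrects the background, normalises the arrays against each other and summarises the probes of a set, so the values are relative signals and carry no read depth. The base of the logarithm is not stated in the labels and was taken as 2, as RMA returns it. The array medians lay between 2.50 and 2.71. No label gives a scan date, slide or batch, so none was tested. Groups were taken from the titles of the samples.

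The value table holds 36685 probe sets. A probe-to-gene table from the platform's annotation covered 15653 of them, of which 14824 had 1 symbol and 829 several; the other 21032 are unnamed here. Only probe sets with 1 symbol were used for named results. Symbols were updated through the Entrez gene number with a RefSeq gene table of assembly GRCr8, in which 14670 of the probe sets matched and 0 symbols changed. The genome build of the array's annotation is not given in the sources used here, and no coordinates are printed. For the 234 genes with several probe sets the one with the highest mean was used, leaving 14557 genes. Genes above the 25th percentile of all values (1.73) in at least 4 arrays were tested, which kept 12912 and left out 1645; of those tested, 4051 have a mean under the 50th percentile (2.58) and are called dim.

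Differences were estimated in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, as 4 group means fitted to all 17 arrays, which share 1 estimate of the spread with 13 residual degrees of freedom. The 9 comparisons were the 6 pairs of groups, the average effect of each diet period and the interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The adjustment was made over the genes, or the lists, of each comparison separately. Values after ± are SEs for differences and SDs for group means. By a rule fixed before the data were examined, up to 12 genes per direction are named by size where at least 5 pass; with fewer, the 5 genes of smallest p in each direction are named, and 12 genes of choline and lipid handling always. From each of 33 gene lists, also fixed then and covering metabolism, stress, cell types and other tissues, passing members or up to 4 with the largest moderated statistic are named. Of 983 entries in the lists, 700 were measured, a count that includes genes matched through a synonym. Such matches brought in genes that were not written entries. Examples are Clec10a, among lipid droplet proteins, and Kcnk13, among NRF2 targets and glutathione enzymes. Lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives. Measures of a whole array were compared with 2-sided exact permutation tests. Correlations of effects were set against 100 random assignments of the arrays, the real one included.

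The gene test was tested on simulated data built from the real means and spreads, with 200 of 12912 genes changed. For DD against DN it recovered 32.8% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 12 false calls. For ND against NN the shares were 20.9%, 74.6% and 97%, with 7 false calls. Simulated genes vary independently of each other, as the real ones do not. On simulated genes that also vary independently, the list test found a list shifted by 0.3 and passed 0 of the other 32. This does not give its error rate on the real genes. On the real arrays, other splits of DD and DN passed a median of 4 lists.

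Alternatives were no filter, a stricter filter at the 50th percentile, all probe sets, the mean of a gene's probe sets, a trended robust variance, array weights, repeated quantile normalisation, centring on the array median, the replicate number as a block, other thresholds, a fit of only the 2 groups compared, a model with no interaction term, and leaving out each array in turn. Added after the data had been seen were array spread (the SD over all probe sets) as a covariate, a fit without DD 3 and DN 3, which had the lowest mean correlations with the other arrays, and the list tests after repeated normalisation and centring. Figures were drawn with matplotlib 3.10.9.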

Results

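Liver gene expression was measured on 17 arrays, each from 1 male rat killed at 24 days of age. All mothers had been made to develop fatty liver by 16 weeks on a choline-deficient diet before mating, and their diet was then either kept deficient or returned to adequate choline, first for pregnancy and again for lactation. This gave 4 groups named by the pregnancy diet and then the lactation diet, with N for adequate and D for deficient choline. NN, ND and DD held 4 livers each and DN held 5, with 1 pup taken per litter, so that the replicates were separate animals from separate litters. The tissue labels name liver, whereas a free-text field on each sample names the prostate cancer line LnCap. Alb, Tf, Ttr and Fgg, which encode albumin, transferrin, transthyretin and a fibrinogen chain made by hepatocytes, were among the 10 genes with the highest mean signal (11.69, 11.46, 11.16 and 10.87 on the log2 scale), and the values were treated as liver. The number of arrays limits the precision of every comparison, and the median standard error of a 2-group difference was 0.17 log2 units between groups of 4.

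Across 9 comparisons of 12912 genes, 1 gene in 1 comparison passed the test, with p adjusted within each comparison and not over the 9 together. Tfec, a transcription factor of the MiT family found in macrophages, fell by 1.45 ± 0.218 (SE) on the log2 scale in DD livers relative to DN livers (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0436), which is a 2.73-fold lower level. Its mean was 2.48 ± 0.14 (SD, n = 4) in DD, 3.93 ± 0.36 (SD, n = 5) in DN, 3.14 ± 0.34 in NN and 3.15 ± 0.47 in ND. Each of the 4 DD livers (2.35 to 2.67) lay below each of the 5 DN livers (3.61 to 4.42). Ccl6, a chemokine, stood next among the lower genes, with a difference of -1.02 ± 0.187 that did not pass (adjusted p = 0.131).

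**Figure D1:**
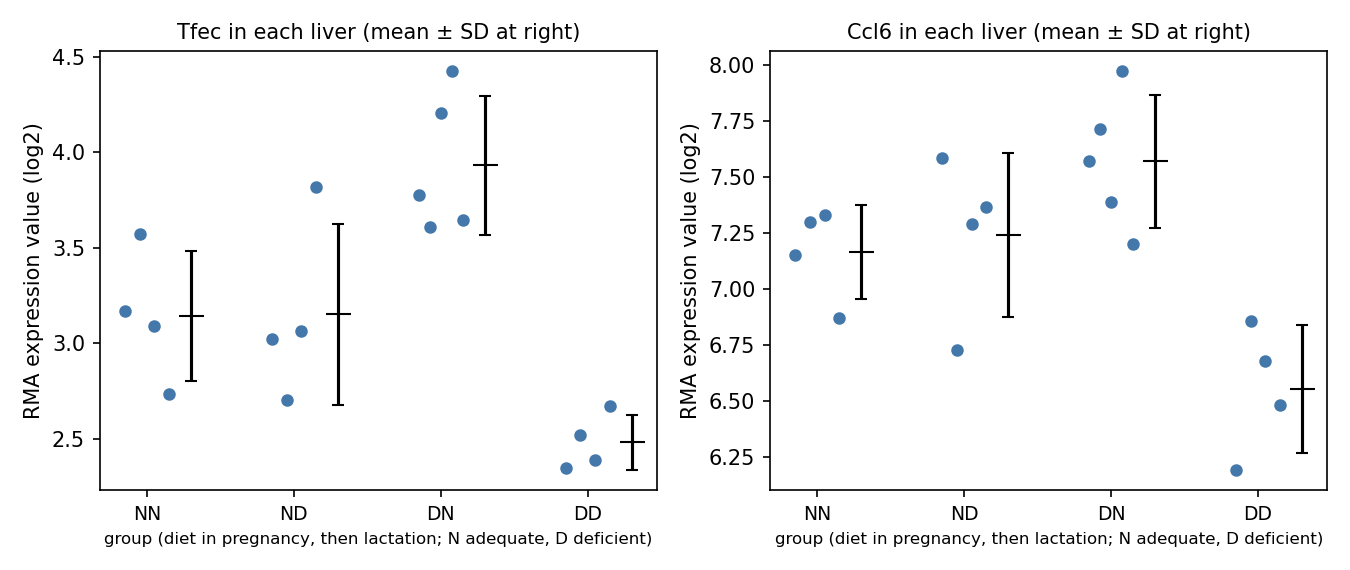
RMA expression values (log2) of Tfec and Ccl6 in each liver, by group, with N for adequate and D for deficient choline in pregnancy and then lactation. Points are single livers (n = 4, 4, 5 and 4) and the bars at the right of each group give the mean ± SD. The DD livers lie at 2.35 to 2.67 for Tfec, below the DN livers at 3.61 to 4.42.

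The DD against DN comparison asks what a deficient lactation diet does after a deficient pregnancy diet. Besides Tfec, the lower genes with the smallest p were Ccl6, Plgrkt (a plasminogen receptor, -0.51 ± 0.102), Ube2m (-0.88 ± 0.187) and Med14, a Mediator subunit (-1.31 ± 0.280). The higher ones were B3galt4 (0.63 ± 0.123), Osm, a cytokine of the interleukin-6 family (0.74 ± 0.148), Slc16a11 (0.77 ± 0.155), Epdr1 (0.77 ± 0.156) and Zfp494l1 (0.79 ± 0.167), each with adjusted p = 0.131. At unadjusted p under 0.05 limma listed 2385 genes, 1012 higher and 1373 lower in DD, where 646 were expected by chance, and 725 with array spread as a covariate. The call on Tfec was lost with no filter on dim genes, with all probe sets tested, with each array centred on its median, with only the DD and DN arrays fitted, with array spread as a covariate, and when any of 12 of the 17 arrays was left out: NN 1, NN 3, ND 1, ND 3, DN 1, DN 3, DN 4, DN 5 or any DD array gave 0 genes. Leaving out an NN or ND array does not change the DD and DN means, so there only the shared spread estimate and the adjusted p moved. The DD mean of Tfec, 2.48, lay under the median of all values on the arrays, 2.58.

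Of the 33 gene lists fixed before the data were examined, 5 were lower in DD than in DN by camera with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment. Cholesterol synthesis genes had a median difference of -0.43, with 14 of 15 members negative (adjusted p = 0.00277, and adjusted p = 0.852 with an estimated correlation), led by Fdft1, squalene synthase (-0.60 ± 0.215), and Srebf2, the regulator of the pathway (-0.61 ± 0.236). Cytochrome P450 and conjugation enzymes had a median of -0.34 with 26 of 31 members negative (adjusted p = 0.0026, and adjusted p = 0.845 with an estimated correlation), among them Cyp2c6v1 (-0.67 ± 0.207) and Cyp17a1 (-0.84 ± 0.274). Fatty acid oxidation genes had a median of -0.27 with 30 of 41 negative (adjusted p = 0.00277, and adjusted p = 0.852 with an estimated correlation), where Etfdh, of the electron transfer chain of beta-oxidation, stood at -0.82 ± 0.191 and Eci2 at -1.09 ± 0.309. Cell cycle genes (median -0.23, 29 of 32 negative, adjusted p = 0.00277, and adjusted p = 0.9 with an estimated correlation) were led by the replication factor Mcm4 (-0.79 ± 0.263) and Prc1 (-0.67 ± 0.256). Acute phase genes (median -0.16, 14 of 18 negative, adjusted p = 0.0325, and adjusted p = 0.845 with an estimated correlation) were led by Cp, ceruloplasmin (-0.78 ± 0.205), and Serpina3n (-0.51 ± 0.137). No member of these lists passed over all genes. Adjusted over the list alone, 3 acute phase members, 1 fatty acid oxidation member and 0 of the other 3 lists passed. None of the 5 calls held with an estimated correlation.

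The spread of the whole array moved with these lists. The SD over all probe sets was 1.67 ± 0.0520 (SD, n = 4) in DD against 1.75 ± 0.0293 (SD, n = 5) in DN (2-sided exact permutation test, p = 0.0476, 0.257 after adjustment over the 6 pairs of groups). The first principal component, with 29.9% of the variance, averaged -17.3 in DD and 15.3 in DN (exact permutation test, p = 0.00794, adjusted 0.0476). With array spread as a covariate, an alternative chosen after the data had been seen, none of the 5 lists passed: the median between DD and DN was -0.03 for P450, -0.01 for fatty acid oxidation and -0.02 for the cell cycle (adjusted p = 0.489, 0.868 and 0.868), but -0.22 for cholesterol synthesis and -0.13 for the acute phase (adjusted p = 0.254 and 0.261). After repeated quantile normalisation cholesterol synthesis, fatty acid oxidation and the acute phase did not pass (medians -0.39, -0.16 and -0.16, adjusted p = 0.0684, 0.0737 and 0.0776).

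**Figure D2:**
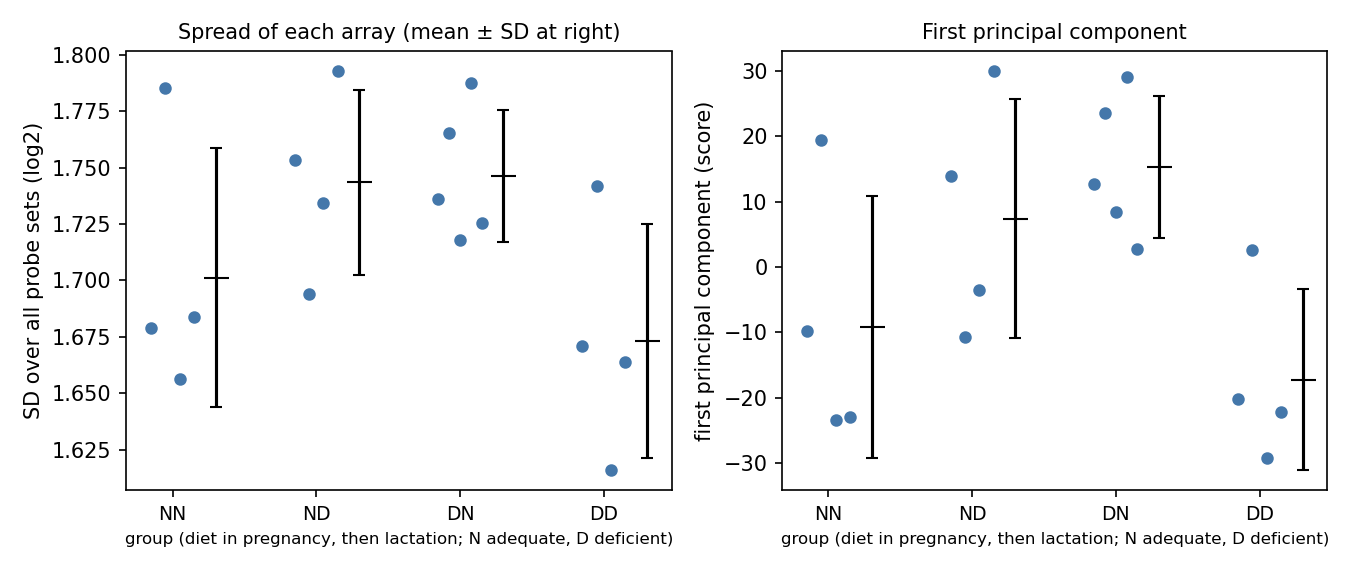
Left, SD of the log2 values over all probe sets of each array. Right, score on the first principal component of the genes tested. Points are arrays by group (n = 4, 4, 5 and 4), and the bars give the mean ± SD. DD arrays average 1.67 in spread and -17.3 on the component, DN arrays 1.75 and 15.3.

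The ND against NN comparison asks about a deficient lactation diet after an adequate pregnancy diet. Limma called 0 genes (smallest adjusted p = 0.889) and listed 598 at unadjusted p under 0.05 against 646 expected, or 368 with array spread as a covariate. Bcl6, a transcriptional repressor, had a mean of 5.06 ± 0.82 in ND and 3.47 ± 0.36 in NN (difference 1.59 ± 0.414), followed among the higher genes by Brwd1 (0.76 ± 0.201), Zmpste24, which processes prelamin A (0.72 ± 0.176), Il6r, the interleukin-6 receptor (0.60 ± 0.149), and Prickle1 (0.50 ± 0.133). On the lower side stood Psph, which completes serine synthesis (-0.75 ± 0.204), Oprd1 (-0.58 ± 0.169), Chpf (-0.48 ± 0.132), Gpr45 (-0.41 ± 0.106) and Inka2 (-0.37 ± 0.106). None of these passed, and Chpf, Gpr45 and Inka2 are dim on these arrays.

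In that comparison 4 lists were higher in ND by camera. Choline oxidation and one-carbon genes had a median of 0.24, with 20 of 28 members positive (adjusted p = 0.00372, and adjusted p = 0.52 with an estimated correlation), such as Aldh1l2 (0.59 ± 0.282) and Cth, of the transsulfuration pathway (0.37 ± 0.185). P450 and conjugation enzymes had a median of 0.23 with 25 of 31 positive (adjusted p = 0.00365, and adjusted p = 0.52 with an estimated correlation), with the male-specific Cyp2c11 at 1.49 ± 0.564 and Fmo1 at 0.72 ± 0.265. Extracellular matrix and stellate cell genes had a median of 0.19 with 29 of 34 positive (adjusted p = 0.00141, and adjusted p = 0.52 with an estimated correlation), led by Dcn, decorin (0.57 ± 0.192), and Mmp2 (0.47 ± 0.186). Gluconeogenesis and amino acid catabolism (median 0.12, 19 of 26 positive, adjusted p = 0.0123, and adjusted p = 0.52 with an estimated correlation) was led by Cdo1 (0.41 ± 0.149) and Tdo2 (0.46 ± 0.173). None of the 4 calls held with an estimated correlation, and adjusted over the list alone 0 members passed. Only the matrix list passed with array spread as a covariate (median 0.08, adjusted p = 0.0468), and choline oxidation, P450 and gluconeogenesis had medians of 0.14, 0.15 and 0.01 (adjusted p = 0.105, 0.305 and 0.105). After repeated quantile normalisation choline oxidation and gluconeogenesis did not pass (medians 0.18 and 0.03, adjusted p = 0.076 and 0.154).

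The DN against NN comparison asks about a deficient pregnancy diet followed by adequate lactation. Mat2a, a synthetase of S-adenosylmethionine, averaged 5.92 ± 0.23 (SD, n = 5) in DN and 6.81 ± 0.38 (SD, n = 4) in NN, a difference of -0.89 ± 0.186 that did not pass in limma (adjusted p = 0.275). Other lower genes were Irx1 (-0.77 ± 0.167), Rem2 (-0.61 ± 0.130), Chpf (-0.58 ± 0.126) and Ntmt1 (-0.55 ± 0.125), of which Rem2 and Chpf are dim. Higher genes were Rab30 (1.40 ± 0.295), Cnot6l, a deadenylase subunit (0.95 ± 0.176), Phaf1 (0.82 ± 0.165), Zmpste24 (0.81 ± 0.167) and Marchf2, a ubiquitin ligase (0.71 ± 0.140), all at adjusted p = 0.275. The call count was 0 with 1732 genes at unadjusted p under 0.05, or 932 with array spread as a covariate. Without array NN 2 limma called 18 genes, 10 higher and 8 lower, including Cnot6l (1.13, adjusted p = 0.0159), Phaf1 (0.96, adjusted p = 0.0314) and Mat2a (-1.05, adjusted p = 0.0417).

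By camera 4 lists were higher in DN than in NN. Bile acid synthesis and transport genes had a median of 0.30 with 12 of 18 positive (adjusted p = 0.0157, and adjusted p = 0.687 with an estimated correlation), led by the hepatocyte uptake transporters Slco1b2 (1.11 ± 0.319) and Slco1a4 (1.11 ± 0.376). P450 and conjugation enzymes (median 0.34, 24 of 31 positive, adjusted p = 0.00599, and adjusted p = 0.687 with an estimated correlation) included Sult1b1 (1.17 ± 0.477) and Cyp2j4 (0.57 ± 0.227). Cell cycle genes (median 0.20, 26 of 32 positive, adjusted p = 0.0157, and adjusted p = 0.747 with an estimated correlation) included Tyms (0.45 ± 0.169) and Cdk1 (0.37 ± 0.148). Extracellular matrix genes (median 0.13, 24 of 34 positive, adjusted p = 0.0458, and adjusted p = 0.687 with an estimated correlation) included Dcn (0.67 ± 0.182) and Hgf (0.61 ± 0.223). None of the 4 calls held with an estimated correlation. Adjusted over the list alone, 1 bile acid gene and 0 members of the other lists passed. None of these 4 lists passed with array spread as a covariate, with medians of 0.21 for bile acids, 0.15 for P450, 0.05 for the cell cycle and 0.02 for the matrix (adjusted p = 0.0902, 0.282, 0.669 and 0.35). Bile acid and matrix genes did not pass after repeated quantile normalisation (medians 0.26 and 0.10, adjusted p = 0.0609 and 0.123). The matrix did not pass after median centring either, although its median was larger (0.19, adjusted p = 0.0518). Without NN 4 0 lists passed.

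The DD against ND comparison asks about a deficient pregnancy diet when lactation is deficient as well. Plgrkt averaged 2.57 ± 0.18 in DD and 3.23 ± 0.11 in ND, a difference of -0.66 ± 0.108 (limma, adjusted p = 0.136). Ptprc, the leukocyte antigen CD45 (-0.65 ± 0.158), Dnase1l3, a nuclease of sinusoidal endothelium (-0.83 ± 0.204), Ccar1 (-0.94 ± 0.226) and Ino80 (-0.54 ± 0.132) followed at adjusted p = 0.55. Higher genes were Gfod2 (0.82 ± 0.147, adjusted p = 0.19), Or10a2 (0.74 ± 0.190), Cdk5 (0.62 ± 0.153), Klk6 (0.49 ± 0.120) and Sft2d2 (0.46 ± 0.107). No gene passed, and 1132 had an unadjusted p under 0.05, 378 higher and 754 lower, or 363 with array spread as a covariate. Gfod2 and Or10a2 are dim on these arrays, with means of 1.74 and 1.79 over all livers. Both averaged under the filter's floor of 1.73 in ND, so the size of their differences is uncertain.

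Lower in DD than in ND by camera were 4 lists. P450 and conjugation enzymes had a median of -0.34 with 27 of 31 negative (adjusted p = 0.00277, and adjusted p = 0.716 with an estimated correlation), among them Cyp2a1 (-0.84 ± 0.217) and Fmo1 (-0.82 ± 0.265). Acute phase genes had a median of -0.20 with 17 of 18 negative (adjusted p = 0.0065, and adjusted p = 0.716 with an estimated correlation), led by Cp (-0.59 ± 0.216) and Lifr (-0.65 ± 0.283). Sinusoidal and vascular endothelium (median -0.23, 15 of 18 negative, adjusted p = 0.0129, and adjusted p = 0.716 with an estimated correlation) was led by Dnase1l3 and by the angiopoietin receptor Tek (-0.48 ± 0.199). Cholesterol synthesis (median -0.36, 13 of 15 negative, adjusted p = 0.0395, and adjusted p = 0.716 with an estimated correlation) was led by Fdft1 (-0.58 ± 0.227) and Ebp (-0.46 ± 0.213). None of the 4 calls held with an estimated correlation. Adjusted over the list alone, 1 P450 member and 1 endothelial member passed. Array spread was 1.67 in DD and 1.74 in ND (2-sided exact permutation test, p = 0.0857, adjusted 0.257), and with it as a covariate none of these 4 lists passed: the cholesterol median turned to 0.01, and those of P450, endothelium and the acute phase were -0.03, -0.01 and -0.08 (adjusted p = 0.837, 0.8, 0.979 and 0.214). Cholesterol synthesis and endothelium did not pass after repeated quantile normalisation (medians -0.32 and -0.10, adjusted p = 0.238 for each). Cholesterol synthesis did not pass after median centring either, although its median was farther from 0 (-0.42, adjusted p = 0.0968).

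**Figure D3:**
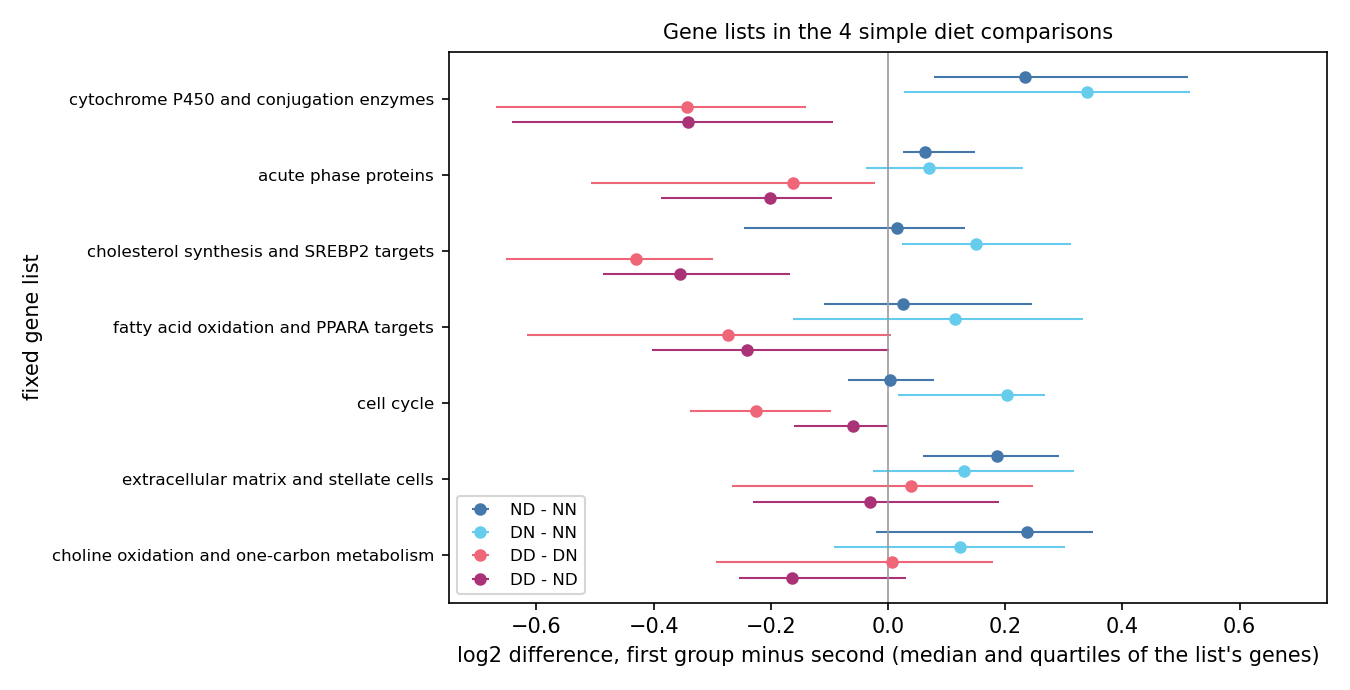
Median log2 difference of the measured genes of 7 fixed lists in the 4 simple diet comparisons, first group minus second, with bars from the lower to the upper quartile of the genes. The P450 and conjugation enzymes lie at 0.23 and 0.34 in the comparisons with NN as the second group and at -0.34 in both comparisons with DD as the first. The 7 lists were chosen after the results were seen.

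The extremes of the design, DD against NN, gave 0 calls in limma (smallest adjusted p = 0.999) and 462 genes at unadjusted p under 0.05, or 625 with array spread as a covariate. Psph again had one of the smaller p values (-0.89 ± 0.204), with Irx1 (-0.70 ± 0.176), Tnfsf15 (-0.57 ± 0.141), Ftsj3-ps1 (-0.57 ± 0.129) and Gpr45 (-0.41 ± 0.106) lower, and Or1j13b (0.77 ± 0.192), Marchf2 (0.66 ± 0.148), Gfod2 (0.64 ± 0.147), Flt3 (0.56 ± 0.147) and Klk6 (0.48 ± 0.120) higher. Extracellular matrix genes were higher as a list (median 0.10, 25 of 34 positive, camera adjusted p = 0.000143, and adjusted p = 0.613 with an estimated correlation), with Col1a1, a fibrillar collagen, at 0.64 ± 0.264, Dcn at 0.62 ± 0.192 and Lum at 0.52 ± 0.159. Lum and Gfod2 averaged under the filter's floor of 1.73 in NN, and Ftsj3-ps1 in DD, so the size of these differences is uncertain. Or1j13b, Flt3 and Gpr45 are also dim on these arrays. Respiratory chain genes were higher (median 0.10, 23 of 35 positive, adjusted p = 0.00493, and adjusted p = 0.775 with an estimated correlation), led by Ndufs8 (0.38 ± 0.160) and Ndufb5 (0.33 ± 0.156). Cholesterol synthesis (median -0.40, 14 of 15 negative, adjusted p = 0.00824, and adjusted p = 0.775 with an estimated correlation), fatty acid oxidation (median -0.17, 33 of 41 negative, adjusted p = 0.0138, and adjusted p = 0.775 with an estimated correlation) and Kupffer cell and macrophage genes (median -0.11, 28 of 33 negative, adjusted p = 0.0268, and adjusted p = 0.775 with an estimated correlation) were lower, with Fdft1 at -0.45 ± 0.227, Eci1 at -0.77 ± 0.247 and the macrophage receptors Vsig4 and Csf1r at -0.82 ± 0.367 and -0.52 ± 0.255. None of the 5 calls held with an estimated correlation, and adjusted over the list alone 0 members passed. Matrix and respiratory chain genes passed with array spread as a covariate, while cholesterol synthesis, fatty acid oxidation and Kupffer cell genes did not (medians -0.29, -0.10 and -0.09, adjusted p = 0.12, 0.474 and 0.0919).

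ND and DN livers, each deprived in a single period, were compared directly. Limma called 0 genes (smallest adjusted p = 0.999), with 365 at unadjusted p under 0.05, or 532 with array spread as a covariate. Among the higher genes in ND were Ppp1r10 (0.78 ± 0.235), Rem2 (0.58 ± 0.130), Safb2 (0.56 ± 0.162), Cnksr3 (0.39 ± 0.108) and Akap17a (0.37 ± 0.103), and among the lower ones Tfec (-0.78 ± 0.218), Rpl36l2 (-0.77 ± 0.173), Rpl36l6 (-0.64 ± 0.180), Slc35f5 (-0.44 ± 0.129) and Sft2d2 (-0.43 ± 0.101). Of these Rem2 is dim on these arrays. Cell cycle genes were lower as a list in ND (median -0.20, 25 of 32 negative, camera adjusted p = 8.66e-05, and adjusted p = 0.933 with an estimated correlation), with Cdk1 at -0.42 ± 0.148, while Aurka stood at 0.31 ± 0.132. Stress response genes were higher (median 0.14, 18 of 24 positive, adjusted p = 0.0354, and adjusted p = 0.933 with an estimated correlation), led by Ddit4 (0.52 ± 0.161) and Ppp1r15a (0.39 ± 0.141), and so were lipid synthesis genes (median 0.24, 14 of 20 positive, adjusted p = 0.0423, and adjusted p = 0.933 with an estimated correlation), led by Pklr (0.67 ± 0.254) and the desaturase Scd (1.01 ± 0.457). None of the 3 calls held with an estimated correlation, and adjusted over the list alone 0 members passed. Without DN 4, 0 lists passed.

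Averaged over both pregnancy diets, a deficient lactation diet gave 0 calls (limma, smallest adjusted p = 0.998) and 407 genes at unadjusted p under 0.05, or 485 with array spread as a covariate. Mt2A, a zinc-binding metallothionein, had a difference of -2.01 ± 0.564, with means of 6.02 ± 1.40 in NN, 5.01 ± 1.25 in ND, 6.41 ± 1.35 in DN and 3.40 ± 1.35 in DD (adjusted p = 0.998). Other lower genes were Tfec (-0.72 ± 0.158), Rpl36l2 (-0.49 ± 0.126), Ccl6 (-0.47 ± 0.136) and Emg1 (-0.38 ± 0.112). Tfec and Ccl6 were not lower in ND than in NN, with means of 3.15 and 7.24 in ND and 3.14 and 7.16 in NN. Higher ones were Or1j13b (0.51 ± 0.132), Cbx8 (0.49 ± 0.121), Zfp494l1 (0.44 ± 0.122), Akap17a (0.31 ± 0.075) and Zfp330 (0.30 ± 0.083), of which Or1j13b and Cbx8 are dim.

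For that lactation average camera passed 8 lists. Higher were choline oxidation (median 0.05, adjusted p = 0.0349, and adjusted p = 0.705 with an estimated correlation) with Bhmt, which uses the choline product betaine (0.37 ± 0.193), and Fpgs (0.34 ± 0.164), and lipid synthesis (median 0.10, adjusted p = 0.0202, and adjusted p = 0.705 with an estimated correlation) with Scd (0.90 ± 0.332) and Pklr (0.55 ± 0.185). So were matrix genes (median 0.06, adjusted p = 0.00132, and adjusted p = 0.705 with an estimated correlation) with Col4a1 (0.49 ± 0.183) and Tagln (0.37 ± 0.154) and periportal genes (median 0.09, adjusted p = 0.0405, and adjusted p = 0.705 with an estimated correlation) with the urea cycle enzyme Ass1 (0.34 ± 0.169). Gluconeogenesis genes were also higher as a list (median 0.10, adjusted p = 0.0349, and adjusted p = 0.803 with an estimated correlation), with Acmsd at 0.36 ± 0.129, although Irs2 stood at -0.51 ± 0.218. Lower were cholesterol synthesis (median -0.19, adjusted p = 0.0014, and adjusted p = 0.705 with an estimated correlation) with Srebf2 (-0.38 ± 0.171), fatty acid oxidation (median -0.11, adjusted p = 0.00132, and adjusted p = 0.705 with an estimated correlation) with Acot2 (-0.62 ± 0.198), and the cell cycle (median -0.12, adjusted p = 0.00132, and adjusted p = 0.803 with an estimated correlation) with Mcm4 (-0.48 ± 0.191). Several of these averages came mainly from 1 pregnancy diet. Between ND and NN the median was 0.015 for cholesterol synthesis, 0.03 for fatty acid oxidation and 0.003 for the cell cycle. Between DD and DN these medians were -0.43, -0.27 and -0.23. Choline oxidation and matrix genes had medians of 0.24 and 0.19 between ND and NN, but 0.007 and 0.04 between DD and DN. None of the 8 calls held with an estimated correlation, and adjusted over the list alone 0 members passed. Periportal genes did not pass after median centring, with a median of 0.08 (adjusted p = 0.0537).

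Averaged over both lactation diets, a deficient pregnancy diet likewise gave 0 calls (limma, smallest adjusted p = 1), with 367 genes at unadjusted p under 0.05, or 646 with array spread as a covariate. Marchf2 (0.47 ± 0.102), Gfod2 (0.45 ± 0.102), Tmem70, an assembly factor of mitochondrial ATP synthase (0.40 ± 0.120), Cep112 (0.40 ± 0.111) and Sft2d2 (0.31 ± 0.074) were higher, and Irx1 (-0.46 ± 0.122), Rem2 (-0.39 ± 0.094), Ftsj3-ps1 (-0.34 ± 0.089), Reep1 (-0.32 ± 0.089) and Pde8b (-0.29 ± 0.081) lower. Stress response genes were lower as a list (median -0.17, 18 of 24 negative, camera adjusted p = 0.00207, and adjusted p = 0.588 with an estimated correlation), led by Psph (-0.48 ± 0.141) and the chaperone cofactor Sdf2l1 (-0.36 ± 0.136), next to Hspa5, the main endoplasmic reticulum chaperone (-0.33 ± 0.138). Respiratory chain genes (median 0.05, adjusted p = 0.0116, and adjusted p = 0.929 with an estimated correlation), with Ndufb5 at 0.30 ± 0.107, and matrix genes (median 0.03, adjusted p = 0.0399, and adjusted p = 0.929 with an estimated correlation), with Dcn at 0.36 ± 0.132 and Lum at 0.33 ± 0.109, were higher. The matrix median was 0.13 between DN and NN but -0.03 between DD and ND. Lum and Gfod2 averaged under the filter's floor of 1.73 in NN, ND and DN, and Ftsj3-ps1 in DN and DD, so the size of their differences is uncertain. Cep112, Rem2 and Reep1 are also dim on these arrays. None of the 3 calls held with an estimated correlation, and adjusted over the list alone 0 members passed. Respiratory chain genes did not pass after repeated quantile normalisation (median 0.04, adjusted p = 0.0867).

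Whether the lactation diet acted differently after the 2 pregnancy diets was tested as the interaction, the DD minus DN difference less the ND minus NN difference. Limma called 0 genes (smallest adjusted p = 0.114), while 2580 had an unadjusted p under 0.05 against 646 expected, 1049 higher and 1531 lower, and 580 with array spread as a covariate. Trpm7, an ion channel with a kinase domain (-1.82 ± 0.374), Ccar1 (-1.59 ± 0.312), Phaf1 (-1.24 ± 0.239), the carboxypeptidase Cpq (-1.12 ± 0.221) and Plgrkt (-0.81 ± 0.149) led the negative side. Chpf (1.04 ± 0.183), Epdr1 (1.01 ± 0.227), Kcns2 (0.98 ± 0.217), the gap junction protein Gja5 (0.90 ± 0.204) and Bicdl2 (0.79 ± 0.169) led the positive side, of which all but Epdr1 are dim on these arrays. Leaving out array NN 2 alone raised the count to 639 genes, 156 higher and 483 lower, with Trpm7 at -2.00 (adjusted p = 0.0269) and Chpf at 1.12 (adjusted p = 0.0219). NN 2 had an array spread of 1.79, where the other NN arrays lay between 1.66 and 1.68.

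P450 and conjugation enzymes carried the largest interaction among the lists, with a median of -0.67 and 26 of 31 members negative (camera, adjusted p = 0.000355, and adjusted p = 0.688 with an estimated correlation). Fmo1 stood at -1.44 ± 0.366, Cyp2j4 at -1.24 ± 0.330, Cyp2a1 at -1.18 ± 0.299 and Sult1a1 at -0.94 ± 0.280. Acute phase genes had a median of -0.22 with 17 of 18 negative (adjusted p = 0.0241, and adjusted p = 0.688 with an estimated correlation), with Cp at -1.06 ± 0.298, Lifr at -0.97 ± 0.390 and Stat3 at -0.76 ± 0.310. Adjusted over the list alone, 7 P450 members and 1 acute phase member passed. With array spread as a covariate the P450 median was -0.15 and the acute phase median -0.11 (adjusted p = 0.282 for each). After repeated quantile normalisation both lists still passed (medians -0.59 and -0.21, camera adjusted p = 0.00179 and 0.0494).

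Gene by gene, the lactation effect after deficient pregnancy ran against the lactation effect after adequate pregnancy. Across 12912 genes, which are not independent replicates, the 2 sets of log2 differences, from separate arrays, correlated at Pearson r = -0.518 and Spearman rho = -0.494, and 31.6% of genes had the same sign in both. Among 100 assignments of the arrays to groups, the real one included, 6 gave a correlation as large in size (2-sided permutation p = 0.06). The pregnancy effects under the 2 lactation diets, from arrays separate from each other, correlated at r = -0.551 and rho = -0.509, where 3 of 100 assignments were as large in size (p = 0.03). The lactation and pregnancy correlations rest on the same 17 arrays and the same 4 group means, so they are not independent findings. The pregnancy correlation was not past 0.05 without NN 3 (p = 0.06), ND 4 (0.11), DN 2 (0.08), DN 4 (0.05), DD 1 (0.07), DD 3 (0.05) or DD 4 (0.06), and with array spread as a covariate it was -0.293 (p = 0.19). The lactation correlation passed with NN 2 (p = 0.01), ND 2 (0.03), ND 3 (0.01), DN 2 (0.04), DD 1 (0.04) or DD 2 (0.04) left out, was -0.301 without ND 4, and did not pass with the covariate (p = 0.19).

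Genes of choline handling that were fixed in advance showed no call in any comparison. Pemt, which makes phosphatidylcholine by methylation, averaged 8.73 ± 0.20 in NN, 8.59 ± 0.38 in ND, 8.62 ± 0.26 in DN and 8.76 ± 0.28 in DD. Pcyt1a, of the cytidine pathway, averaged 4.53 in NN and 4.48 in DN. Chdh, which oxidises choline, averaged 6.62 in NN and 6.51 in DD. Bhmt averaged 9.39 ± 0.25 in NN and 9.90 ± 0.32 in ND (difference 0.51 ± 0.281), and Gnmt 7.34 ± 0.60 and 7.79 ± 0.54 in the same groups (0.45 ± 0.372). Mat1a, the S-adenosylmethionine synthetase of adult liver, stood at -0.29 ± 0.136 in DD against DN and at 0.30 ± 0.136 in DN against NN (adjusted p = 0.263 and 0.358). Plin2, which coats lipid droplets, averaged 7.65 ± 0.33 in NN and 7.07 ± 0.61 in DD. Mttp, which loads lipid onto apolipoprotein B, averaged 7.15 ± 0.28 and 6.86 ± 0.36 there. Cpt1a, the entry step of fatty acid oxidation, averaged 5.54 ± 0.76 in NN, 6.15 ± 0.76 in ND, 6.48 ± 1.16 in DN and 5.85 ± 0.49 in DD. Its differences were 0.94 ± 0.500 for DN against NN and -0.63 ± 0.500 for DD against DN (adjusted p = 0.409 and 0.511 in limma). Chka and Fasn were not analysed here. The list of phosphatidylcholine synthesis and choline transport, with 16 genes measured, passed in 0 of the 9 comparisons (camera, adjusted p = 0.935 in ND against NN and 0.907 in DD against DN).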

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

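The tests of explanations and of other splits below, the 2 comparisons with random lists matched on slope among them, were chosen after the results they bear on had been seen.

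By a test of the interaction term with camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.688 for each), the lactation effect differed between the 2 pregnancy diets for P450 and conjugation enzymes (median -0.67) and for acute phase genes (-0.22). Array-wide spread is a candidate cause: with it as a covariate 580 genes had an unadjusted p under 0.05 for the interaction, against 2580 without it and 646 expected by chance. The acute phase list lay at percentile 24.4 of 10000 random lists drawn from the same 20 bins of slope against array spread. That test leaves spread open as its cause. The P450 list lay at percentile 0.49, below the matched range of -0.59 to -0.19. Its median slope was 4.09, against 0.04 for all genes. Genes within an outer bin can differ in slope, so the test cannot decide for P450. With the covariate, which takes each gene's own slope, the P450 median was -0.15 (adjusted p = 0.282). After repeated quantile normalisation, which gives the arrays 1 distribution of values, both lists still passed by camera. The P450 median was then -0.59 (adjusted p = 0.00179) and the acute phase median -0.21 (adjusted p = 0.0494). A mislabelled or deviating NN 2 as the source would bring the correlation of lactation effects nearer to 0 when left out, yet without it the correlation was -0.626, farther from 0. An effect of the diets stays open and untested, since array spread itself could follow the state of the liver.

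Tfec between DD and DN was set against 2 explanations. With array spread as a covariate its difference was -1.12 ± 0.224, from -1.45 ± 0.218, so it shrank at a near equal SE. Its unadjusted p in limma went from 3.38e-06 to 0.000114, and the call ended (adjusted p = 0.876). The adjusted p also depends on the other genes, and over all genes 725 had an unadjusted p under 0.05, against 2385 without the covariate. Spread may thus contribute. Tfec was picked as the gene of smallest p, so the size left cannot tell spread together with chance from another cause. Fewer macrophages in the DD livers would lower macrophage genes alike. The 33 Kupffer cell and macrophage genes had a median of -0.11 (SD of members 0.392). Of the 6 most abundant, Cd74 stood at -0.54, Cd5l at -0.11, C1qb at 0.07, Clec4f at 0.20, Marco at 0.28 and C1qa at 0.49. A loss as large as the Tfec difference was thus not seen in these genes. Since Tfec was picked for its small p, this cannot weigh against a smaller loss together with chance. Going with such a loss, 22 of the 33 were negative, 5 were lower and 0 higher at unadjusted p under 0.05, 1 passed adjusted over the list alone, and Vsig4 stood at -1.47 ± 0.348, so some loss of macrophages stays open. The diets and a change within macrophages stay open as well, and 8 of 100 splits of these 9 arrays gave as many calls as the real 1, so chance is not excluded, and the highest other split, with 221, points to a structure of the samples whose source was not tested.

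Other splits of the arrays gave as many genes at unadjusted p under 0.05 in 10 of 35 for ND against NN (598, highest other 2643), 10 of 100 for DN against NN (1732, highest other 2552), 4 of 35 for DD against ND (1132, highest other 2239), 20 of 35 for DD against NN (462, highest other 1582), 67 of 100 for ND against DN (365, highest other 1835), 52 of 100 for the lactation average (407, highest other 2126) and 66 of 100 for the pregnancy average (367, highest other 2841), so chance is not excluded for these. Highest counts several times the real one point to a structure of the samples, whose source was not tested. Chance is not excluded for the lactation correlation (6 of 100 as large in size, -0.518, farthest other -0.655). Each taken alone and with no adjustment for the number of split tests, it is excluded at 0.05 for DD against DN (3 of 100, 2385, highest other 2540), for the interaction (2 of 100, 2580, highest other 2692) and for the pregnancy correlation (3 of 100, -0.551, farthest other -0.575). Over all the split tests together chance is not excluded. The DD against DN, interaction and pregnancy results share arrays, so they are not independent of each other. With array spread as a covariate these counts were 725 and 580, against 646 expected, and the pregnancy correlation was -0.293 (p = 0.19). That correlation was also not past 0.05 when any of NN 3, ND 4, DN 2, DN 4, DD 1, DD 3 or DD 4 was left out (p from 0.05 to 0.11).

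For the lists past the threshold, as many passed in 20 of 35 splits for ND against NN (4, highest other 14), 44 of 100 for DD against DN (5, highest other 12), 54 of 100 for DN against NN (4, highest other 15), 23 of 35 for DD against ND (4, highest other 14), 12 of 35 for DD against NN (5, highest other 13), 78 of 100 for ND against DN (3, highest other 12), 16 of 100 for the lactation average (8, highest other 17), 75 of 100 for the pregnancy average (3, highest other 15) and 80 of 100 for the interaction (2, highest other 13). Chance is excluded for none of these counts.

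One liver stood apart from the others of its group in 27 of 504 group-by-quantity tests, close to the 5% that chance gives. ND 2 did so for Oprd1 (2.86), Zfp330 (4.31), Mt2A (6.87), Aldh1l2 (5.51), Amd1 (4.07) and Ccna2 (3.55). NN 3 did for Cnksr3 (4.25), Bicdl2 (2.93), Dcn (2.64) and Csf1r (4.30), and NN 2 for Mt2A (8.09) and Ccna2 (4.30). DD 3 was apart for Il6r (6.24), Zfp494l1 (3.95), Sft2d2 (5.50) and Eci1 (5.81), and DD 2 for Eci2 (7.25), Tek (3.73) and Aurka (4.36). DN 4 was apart for Ino80 (3.94), Dnase1l3 (6.99) and Acaa2 (9.93), ND 4 for B3galt4 (3.34) and Ptprc (3.83), NN 4 for Gnmt (6.45), ND 1 for Pcyt1a (4.78) and ND 3 for Lum (1.60), which is under the filter's floor of 1.73. None of the 3 whole-array measures tested this way was apart.

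Outside the named genes, 1 unnamed probe set, 17744312, was lower in ND than in DN when all probe sets were tested (log2 difference -0.75, adjusted p = 0.0234 in limma).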

How the results depend on the processing

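Array spread as a covariate, the fit without DD 3 and DN 3, the permutations of replicate numbers, and the list tests after repeated normalisation and centring were chosen after the data had been seen. Signal over background limits the dim genes, 4051 of the 12912 tested, and the cause of a change was not tested unless stated.

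The single call between DD and DN became 0 genes with no filter, with all probe sets, with median centring, with only the 2 groups fitted, with array spread as a covariate and without DD 3 and DN 3. With all probe sets 1 was called between ND and DN. Leaving out 1 array gave 0 to 1 genes between DD and DN, 0 to 18 between DN and NN and 0 to 639 for the interaction, the highest values without NN 2; the other 6 comparisons had 0 genes throughout these leave-outs.

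Replicate numbers were not taken to pair the animals, since the labels do not say that they do. The correlations of same-number arrays, after removal of group means, lay on both sides of 0 (from -0.454 to 0.533), which cannot decide on pairing. Their average was 0.0671, against -0.0185 for arrays of different numbers (1-sided permutation test over 10000 orders, p = 0.10). Of the 17 arrays 8 correlated best with their own number, where such orders gave 3.78 on average (p = 0.0478), a hint from the data and not the design. Mt2A was highest at number 2 in each of the 4 groups, and was lower in ND than in NN and in DD than in DN at each number from 1 to 4, which is a hint from the data only. With the number as a block, limma called 3 genes between DD and DN, Tfec (-1.52), Mt2A (-3.44, adjusted p = 0.00297) and Mt1f (-2.18), and 1 for the lactation average, Mt2A (-2.23, adjusted p = 0.00865). List counts with the block were 1 for DN against NN (higher), 5 for ND against DN (2 higher, 3 lower) and 1 for the pregnancy average (lower). The block changed no other count by over 1.5 times.

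Counts of lists became 0 in all 9 comparisons with an estimated correlation and 0 with fry, which drop the preset correlation of 0.01 between genes. With no filter they were 10 for ND against NN (9 higher, 1 lower), 1 for the pregnancy average (lower) and 9 for the interaction (1 higher, 8 lower). Repeated quantile normalisation gave 3 for DD against DN (1 higher, 2 lower) and 5 for the interaction (2 higher, 3 lower), where all had been lower before, and 28 of the 38 list calls stayed past the threshold; with median centring 35 did. No list median changed sign under either. With array spread as a covariate 17 of the 38 stayed, but none of those of DD against DN, DN against NN, DD against ND or the interaction. The lists that passed there went the other way: 2 for DD against DN (higher, against 5 lower without the covariate), 1 for DN against NN (lower, against 4 higher) and 2 for DD against ND (higher, against 4 lower), with 0 for the interaction. The pregnancy correlation was -0.293 (p = 0.19). Without DD 3 and DN 3 the counts were 7 for the pregnancy average (6 higher, 1 lower) and 1 for the interaction (lower).

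Leaving out each array in turn, lists past the threshold ranged from 3 to 14 in ND against NN, 2 to 7 in DD against DN, 0 to 7 in DN against NN, 3 to 7 in DD against ND, 2 to 7 in DD against NN, 0 to 5 in ND against DN, 3 to 10 for the lactation average, 1 to 5 for the pregnancy average and 2 to 9 for the interaction. The highest counts came without NN 2 for ND against NN (14), without NN 2 or DN 2 for DN against NN (7) and the pregnancy average (5), without DN 2 for DD against DN (7), without ND 2 or DD 1 for DD against ND (7), without ND 2, DD 1 or DD 2 for the interaction (9), without DD 3 for DD against NN (7) and the lactation average (10), and without DN 3 or DN 5 for ND against DN (5). The lowest came without DN 4 for DD against DN (2), ND against DN (0) and the lactation average (3), without NN 4 for DN against NN (0), without DD 2 for DD against NN (2) and without NN 3, NN 4, DN 5 or DD 2 for the pregnancy average (1). The correlation of lactation effects ranged from -0.626 to -0.301 and that of pregnancy effects from -0.615 to -0.400, with the ends without NN 2 and without ND 4. Their p ran from 0.01 to 0.22 for lactation and from 0.01 to 0.11 for pregnancy.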

Other observations

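The test on the glucocorticoid list was chosen after the value of Mt2A had been seen.

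Cell types other than hepatocytes showed no list past the threshold between DD and DN. The smallest adjusted p among them was that of sinusoidal and vascular endothelium, with a median of -0.10 over 18 genes, 12 of them negative (camera, adjusted p = 0.201), and 2 members that passed adjusted over the list alone. Its members Dnase1l3 and Tek stood at -0.65 ± 0.194 and -0.60 ± 0.188. Matrix and stellate cell genes had a median of 0.04 over 34 genes (adjusted p = 0.748). By camera the median difference was 0.10 for 21 lymphocyte genes (adjusted p = 0.646), 0.07 for 14 neutrophil genes (0.503), 0.05 for 19 erythroid genes (0.774), 0.08 for 13 cholangiocyte and progenitor genes (0.225) and -0.11 for 33 Kupffer cell and macrophage genes (0.225). Pancreas, muscle and adipose markers, 20 genes, had a median of 0.03 (adjusted p = 0.296). Immediate early genes had a median of 0.19 in DD against DN and -0.21 in ND against NN (adjusted p = 0.0892 and 0.051), and circadian clock genes -0.35 in DD against ND (adjusted p = 0.0969). Lipid droplet proteins, the genes nearest to stored fat, had medians of -0.10 in ND against NN and -0.15 in DN against NN (adjusted p = 0.288 and 0.233). The measured list also held Clec10a, which was not among its written entries.

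Mt2A varied widely between livers of a group: DD livers read 2.12 to 5.21, DN livers 4.69 to 7.92, and NN 2 read 8.09 where the other NN livers read 5.00 to 5.51. Between DD and DN Mt2A differed by -3.01 ± 0.776 (adjusted p = 0.131). Mt1f, another metallothionein, named after its value was seen, differed by -1.72 ± 0.619 (adjusted p = 0.17). A weaker glucocorticoid and fasting response in livers from deficient lactation was considered as a candidate explanation. The other 18 measured genes of that list had a median lactation average of 0.0932, with 11 above 0 and an SD of members of 0.349. Members lay on both sides of 0, so these values neither bear out nor exclude the explanation, which stays open. Zinc supply was not tested.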
